A study of Mus musculus with 4 samples.

How the data were processed

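Per the labels' protocols, total RNA was isolated with a Qiagen kit from the kidney medulla of mice at postnatal day 14, in 4 samples. They give Eurofins GATC Biotech for library preparation and Illumina sequencing. The strain is given as mixed C57BL/6. Groups and replicate numbers were taken from the sample titles, which number 2 wild-type and 2 knockout samples. That each sample came from its own animal is inferred from this numbering.

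The deposited table holds 1 signal value per gene and library, which the authors made by dividing gene read counts by 1 size factor per library; this is read from the values, since within each column they are whole multiples of 1 step. The steps were 0.985 and 0.994 in the wild-type and 1.07 and 0.942 in the knockout columns, and 100% of the values came out whole within 0.001 after division by the step. For the second wild-type library the step lies close to 1, but its values were not whole before division, such as 3.97594 for Adgra1 and 45.7233 for Sox9. Per the submitters' processing notes, fastp 0.20.1, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 2.11.40.7 were used with the builds mm10 and GRCm38. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical paralogs and of overlapping or antisense genes can therefore be split or shared, and counts of such genes are uncertain. Because counts are per whole gene, reads from exons that Cre leaves in place still count for the targeted gene.

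The table had 27179 Entrez gene IDs, of which 25275 were matched to a symbol in a RefSeq gene table of GRCm38.p6. The 1904 others held 0.325% to 0.339% of the totals, and 386 of them were tested. Coordinates are those of that table, on the build of the deposited values. The reads recovered per library ranged from 36482238 to 40784436, and 18972 to 19249 genes were detected per library. Intervals and floors from these reads cover counting error only, since reads without molecular identifiers are not independent molecules. Between replicates the chi-square per degree of freedom of the recovered reads was 23.2 in the wild-type and 17.6 in the knockout group, so no library was a copy of another.

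The main test was limma 3.58.1 in R 4.3.3, with a variance trend, on log2(value + 1), two-sided, for the 16253 genes with a mean of at least 10 over the 4 libraries; 10926 genes were not tested. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 6.96 in all after pooling the spread across genes. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test) called 4190 genes higher and 4113 lower, and shared 8209 calls with limma. DESeq2 1.42.0 called 4006 higher and 3817 lower, and shared 7722.

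Before the data were examined, 34 gene lists were fixed: subunits and regulators of the Arp2/3 complex, other actin, junction and adhesion genes, markers of the tubule segments and of other kidney and blood cells, and injury, matrix, inflammatory and metabolic genes. Lists with at least 5 tested members, 32 in all, were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. With 2 residual degrees of freedom the estimated correlation is itself uncertain, and camera was run with it as an alternative, next to fry. The list of mitochondrially encoded genes had 0 members in the table, and the sex-linked list was read as values only.

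The genes to name were also fixed by rule before the data were examined. They are the Arp2/3 subunits, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 and separate ranges, leaving out predicted genes, and of each list up to 4 members with the smallest adjusted p. Genes named outside that rule were chosen after their values were seen. Some genes, including members the rule selects, are not reported here. Where a group had no reads, a fold was computed against a floor of 3 reads over the group, and with 1 to 3 reads the ratio is given with its exact 95% interval. The alternatives were other pseudocounts, filters, scalings and variance models, edgeR and DESeq2, a block for the replicate number, and leaving out each library in turn; in the last case the lone library is assumed to vary like the other group.

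The tests were tested on simulated data with 15806 genes, drawn from the means of the wild-type libraries, with 98 genes changed by each of 2 sizes. Genes were drawn independently of each other, and far fewer were changed than the 51.2% called in the real data. The shares below describe that setting. limma recovered 81.6% of the genes changed by a log2 of 1 and 94.9% of those changed by a log2 of 2. Of its calls 13.5% were unchanged genes, against 13.4% for edgeR and 18% for DESeq2, each above the nominal share, so counts of calls hold more false calls than the threshold states where few genes change. A raised list of 22 members was called by camera at the preset correlation (adjusted p = 4.7e-73), which also called 1 other list, and by fry (adjusted p = 0.00302), but not with an estimated correlation (adjusted p = 0.0757). The members of that list were drawn without correlation, so the simulation does not test whether the preset correlation suits these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.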

Results

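The dataset held 4 libraries of mRNA sequencing of the mouse kidney medulla at postnatal day 14. The medulla is the inner part of the kidney that holds the loops of Henle and the collecting ducts. Wild-type controls gave 2 libraries and mice labelled as Actr3 knockouts gave 2, each taken to be from its own animal. Actr3 encodes Arp3, a core subunit of the Arp2/3 complex that nucleates branched actin filaments. In the knockout the floxed gene was combined with a Cre transgene under the promoter of Cdh16, the kidney-specific cadherin of tubule epithelium. The comparison asked how the medullary transcriptome differed between the groups. The reads recovered per library were 40453242 and 40342530 in the wild-type libraries and 36482238 and 40784436 in those labelled knockout. Log2 values correlated at r = 0.989 across genes between the wild-type libraries and at 0.990 between those labelled knockout, against at most 0.916 across the groups (genes are not independent replicates).

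The targeted gene was higher, not lower, in the libraries labelled knockout. Actr3 (Entrez 74117, chromosome 1, 125392905 to 125435727, GRCm38) had normalized read counts of 8065 and 7275 in the wild-type libraries and 12587 and 12480 in those labelled knockout. The means were 7670 ± 558 (SD, n = 2) and 12534 ± 75.2 (SD, n = 2), a 1.63-fold difference, with a log2 difference of 0.71 (SE 0.082, limma adjusted p = 0.000494). A whole-gene count cannot show whether an exon was deleted, so this value neither checks the deletion nor shows whether the labels are right. For this reason the groups are called WT-labelled and KO-labelled below, and every direction given here rests on those labels.

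Other subunits of the complex rose as well in the KO-labelled libraries. Of the 10 subunits, 7 rose, none fell and 3 did not pass the threshold, and adjusted over the list alone 8 rose. The largest of these rises was that of Arpc1b, the isoform abundant in blood-lineage cells, from 3162 ± 60.0 to 9278 ± 646 (SD, n = 2), a log2 difference of 1.55 (SE 0.081, limma adjusted p = 2.17e-05). Arpc2, Arpc3, Arpc4 and Arpc5 had log2 differences of 0.59, 0.61, 0.51 and 0.59. Actr2, which encodes Arp2, rose by a log2 difference of 0.35 (adjusted p = 0.0116), a call lost without WT replicate 2 (adjusted p = 0.0525) and without KO replicate 1 (0.0548). Arpc1a, Arpc5l and the low-abundance Actr3b had log2 differences of 0.13, 0.17 and 0.87 and did not pass the threshold; Actr3b passed it with a pseudocount of 5 (adjusted p = 0.0499) and with no variance trend (0.0393). The list median was 0.59, and the list as a group was called higher by limma's camera test (adjusted p = 0.000635; adjusted p = 0.434 with an estimated correlation). Macrophage and dendritic cell markers rose in the same libraries (21 of 22, median 2.64), and these counts do not show in which cells the subunits rose.

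**Figure D1:**
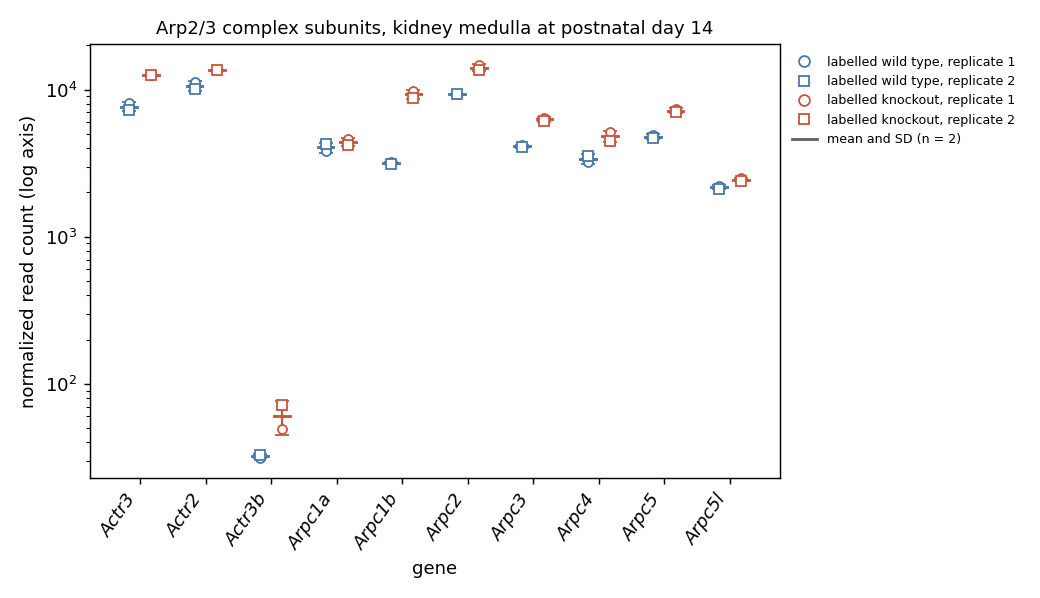
Normalized read counts (log axis) of the 10 Arp2/3 subunits in each library, blue for WT-labelled and red for KO-labelled, with bars for the mean and SD (n = 2). Actr3 lies at 8065 and 7275 in the WT-labelled libraries and at 12587 and 12480 in the KO-labelled libraries, and Arpc1b shows the largest separation among the abundant subunits.

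Among 16253 genes tested, 4277 were higher and 4051 lower in the KO-labelled libraries (limma, adjusted p under 0.05), which is 51.2% of those tested. With a log2 difference of at least 1 in either direction, 1745 were higher and 1536 lower. Log2 differences are KO-labelled minus WT-labelled on the log2(value + 1) scale, which understates the change of low genes, and folds are ratios of the group means of normalized counts. Genes named below that no rule fixed in advance had selected were chosen after their values were seen; they are Cdh16, Slc12a1, Umod, Cldn14, Cldn11, Cldn16, St6gal1, Tmem45b, Aqp2, Scnn1b, Gata3, Hoxb7, Spink8, Kit, Tspan8, Hspb8, Slc38a2, Nfat5, Slc34a1, Kap, Slc12a3, Trpv5, Cdkn1c, Nes, Tfrc, Epb42, Ndufa2, Krt7, Spp1, Havcr1, Sox9, Vcam1, Rgs5, Fbln5, Tcf21, Acta2, Fhl2, Amotl2, Lats2, Crim1, Wasf3, Pick1, Abi2, Fmnl1, Diaph3, Pfn1, Fmn1, Cldn3, Cldn7, H2-Aa, Cxcl12, Ifi44, Ifit3, Gbp2, Sesn1, Klf2, Hspa1b, Hsph1, Hspa1a, Kif23, Rrm2, Lhx1, Ret, Crym, Pkd2, Bicc1, Ift57, Pkhd1, Atp6v0d2, Rps6, H1f2, H2ac6, H1f10, Itgax, Trem2, Col3a1, Fn1, Il6 and Tnf.

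The largest rises were in genes that were close to silent in the WT-labelled medulla. Mmp7, a matrix metalloproteinase, went from 5.91 and 1.99 to a mean of 2828 ± 694 (SD, n = 2), a log2 difference of 9.26 (SE 0.41, limma adjusted p = 1.27e-05; chromosome 9, 7692090 to 7699585, GRCm38). Wnt7a, a secreted Wnt ligand, had 1 read in the WT-labelled libraries together and 1210 in the KO-labelled ones, a ratio of 1230 (exact binomial 95% interval 220 to 48500, counting error only). Cartpt, a neuropeptide precursor, and Vat1l had no reads in either WT-labelled library, and were at least 123-fold and at least 113-fold higher in the KO-labelled libraries against a floor of 3 reads over the group. Ltbp2, a matrix protein that belongs to the latent TGF-beta binding family, rose from 31.1 ± 7.5 to 4886 ± 1213, and Fgg, the gamma chain of fibrinogen, from 21.8 ± 5.74 to 3383 ± 97.6 (SD, n = 2). Adgra1, Crisp1, Cxcl5 and Cadm3, the last a cell adhesion molecule and Cxcl5 a neutrophil-attracting chemokine, completed the 10 largest rises, with log2 differences of 7.57, 7.07, 6.83 and 6.76.

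The deepest fall was that of Egf, the epidermal growth factor precursor made by the thick ascending limb and distal convoluted tubule. It went from 53057 ± 6447 to 620 ± 125 (SD, n = 2), an 85.6-fold lower mean and a log2 difference of -6.43 (SE 0.15, limma adjusted p = 2.87e-06; chromosome 3, 129677574 to 129755322, GRCm38). Slc4a1, the chloride-bicarbonate exchanger of intercalated cells and red cells, fell 54.3-fold, from 4503 ± 24.9 to 82.9 ± 4.05. The linker histone genes H1f3 and H1f4 had log2 differences of -6.29 and -5.52, and the basal keratin Krt15 one of -5.99. Nccrp1 also fell, by a log2 difference of -5.49, although its WT-labelled values of 2682 and 12802 differed widely. Lhfpl3, Rph3a, Nr2e3 and Hpd, with log2 differences between -5.73 and -5.07, completed the 10 largest falls; Nr2e3 encodes a nuclear receptor and Hpd an enzyme of tyrosine breakdown.

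Most markers of the medullary tubule segments were lower in the KO-labelled libraries. In the thick ascending limb, the salt-reabsorbing segment of the loop of Henle, 16 of 20 markers fell and 3 rose. Slc12a1, the apical sodium-potassium-chloride cotransporter, fell from 240850 ± 1374 to 33986 ± 7404 (SD, n = 2), a 7.09-fold lower mean. Tmem207 fell 26.8-fold and Wfdc15b 11.8-fold. Umod, uromodulin, a secreted protein of the same segment, did not follow them: its counts of 136828 and 143709 stood against 203680 and 138033 (log2 difference 0.26, limma adjusted p = 0.294; 0.85 and adjusted p = 0.00151 after quantile normalization). The members that rose were the tight junction genes Cldn14, Cldn11 and Cldn16, with log2 differences of 2.65, 2.49 and 0.28. The call of Cldn16 (adjusted p = 0.0476) was lost in most other settings, and without KO replicate 1 only 1 member of the list rose.

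In the collecting duct, 13 of 20 principal cell markers fell and 2, St6gal1 and Tmem45b, rose by log2 differences of 0.99 and 0.49. Aqp2 and Aqp3, the apical and basolateral water channels, fell 5.40-fold and 7.63-fold, Rhcg, an ammonia transporter, 5.67-fold, and Kcnj1, the ROMK potassium channel, 5.59-fold. Scnn1b, a subunit of the epithelial sodium channel, and the lineage transcription factor genes Gata3 and Hoxb7 had log2 differences of -0.11, 0.05 and 0.23 and did not pass the threshold; Hoxb7 passed it after quantile normalization (adjusted p = 0.0442). Among the acid-base transporting intercalated cells, 17 of 20 markers fell and 1 rose. Foxi1, the transcription factor that specifies these cells, fell 4.17-fold, the proton pump subunit gene Atp6v1b1 3.94-fold and Aqp6 5.03-fold, alongside Slc4a1. Atp6v0d2, another proton pump subunit gene, did not follow them (log2 difference 0.01, limma adjusted p = 0.949). Spink8 was the member that rose, by a log2 difference of 3.14, and Kit had one of 0.34 (adjusted p = 0.111), called only without KO replicate 2 (log2 difference 0.54, adjusted p = 0.0124).

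In the thin limbs of Henle, 12 of 16 markers fell and 2 rose. Prox1, a transcription factor, fell 7.31-fold and Corin 7.19-fold. The members that rose were Cp, ceruloplasmin, the copper-carrying ferroxidase, by 7.78-fold, and Tspan8 by a log2 difference of 0.35. Of 24 genes of urine concentration and the osmotic response, 20 fell and 2, Hspb8 and Slc38a2, rose by log2 differences of 1.42 and 0.37. Slc6a12, the betaine transporter, fell 32.5-fold, and Slc5a3, the myo-inositol transporter, 3.79-fold. Nfat5, the transcription factor that drives these osmolyte genes, fell by a log2 difference of -0.48 (SE 0.093).

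The medians of these 5 lists were -1.53 for the thick ascending limb, -0.80 for principal cells, -1.91 for intercalated cells, -0.995 for thin limbs and -0.92 for urine concentration. Camera called each of them lower, with adjusted p of 2.75e-06, 0.000223, 4.79e-07, 0.000438 and 4.84e-07. These calls were lost with an estimated correlation (adjusted p = 0.479, 0.479, 0.31, 0.479 and 0.31 with an estimated correlation, in the same order). Adjusted over the list alone, the falls numbered 16, 13, 17, 12 and 20 and the rises 3, 3, 1, 2 and 2. Cdh16, whose promoter drives Cre here, was itself 2.33-fold lower, at 92052 ± 10890 against 39571 ± 2667 (SD, n = 2).

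**Figure D2:**
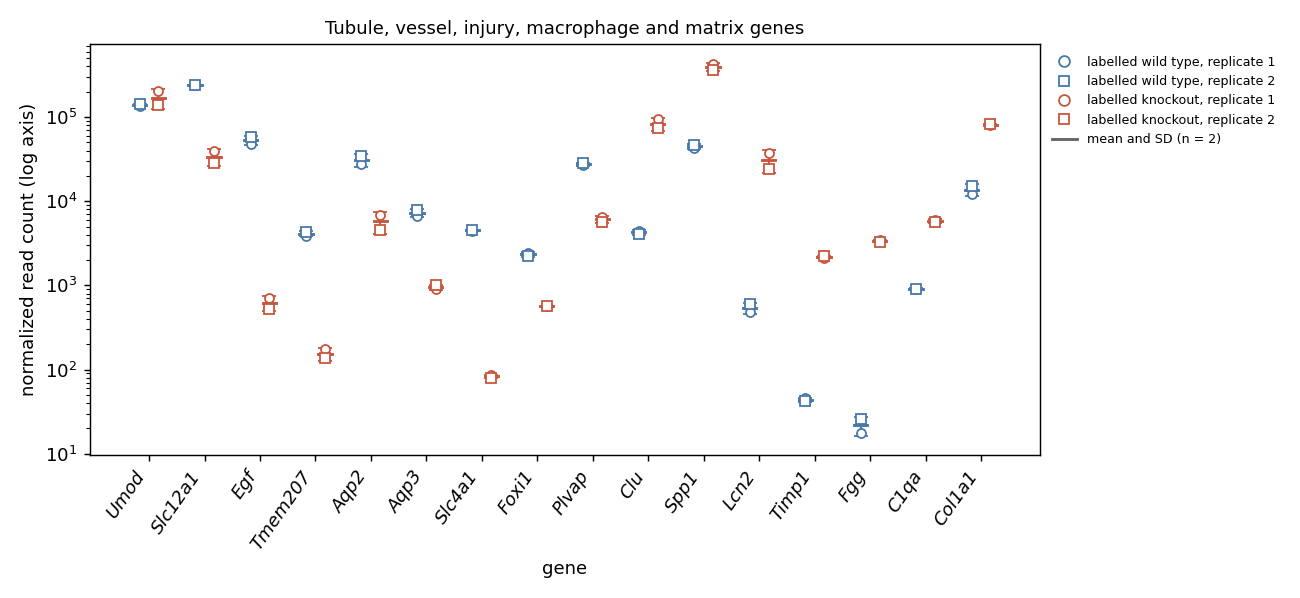
Normalized read counts (log axis) of 16 genes in each library, blue for WT-labelled and red for KO-labelled, with bars for the mean and SD (n = 2). Egf, Slc12a1, Aqp2, Slc4a1 and Plvap lie lower in both KO-labelled libraries, Lcn2, Clu, Timp1 and C1qa lie higher, and Umod overlaps between the groups at 136828 to 203680.

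Markers of cortical segments, which a medullary dissection can carry along, were examined too. Of 25 proximal tubule markers 19 fell and none rose, with a median log2 difference of -1.35 (camera adjusted p = 1.09e-05; adjusted p = 0.479 with an estimated correlation), and adjusted over the list alone 21 fell. The falls numbered 10 with no variance trend and 6 with a robust one, and the fry test did not call the list (adjusted p = 0.102). Slc6a19, a neutral amino acid transporter, fell 5.47-fold and Slc7a13 6.07-fold. These markers also varied between replicates: the median difference of the list was -0.81 between KO replicates 1 and 2 and -0.41 between WT replicates 1 and 2. Slc34a1, the phosphate cotransporter, read 9589 and 18430 in the WT-labelled and 1171 and 3902 in the KO-labelled libraries. Kap, the kidney androgen-regulated protein gene, fell 2.61-fold, a call lost without WT replicate 1 (adjusted p = 0.0768). In the distal convoluted tubule 7 of 12 markers fell and 3 rose, and adjusted over the list alone 7 fell and 4 rose. Slc12a3, the thiazide-sensitive cotransporter, read 877 and 3085 against 177 and 334, while Trpm6, a magnesium channel gene, and Trpv5, a calcium channel gene, rose by log2 differences of 2.51 and 3.37 and Slc8a1, a sodium-calcium exchanger gene, by 0.88. The list was not called (median -1.99, camera adjusted p = 0.127), but was without WT replicate 1 (adjusted p = 0.0202; adjusted p = 0.72 with an estimated correlation and all libraries), and with a robust variance trend 4 members fell. Without WT replicate 2 the median was -1.28 (adjusted p = 0.249), with 4 of 11 markers higher and 7 lower. Its median differed by -1.26 between WT replicates 1 and 2. Podocyte markers went both ways, with 5 lower and 3 higher of 12 (camera adjusted p = 0.384); adjusted over the list alone 6 were lower and 3 higher. Among them Podxl, Clic5 and Cdkn1c fell by log2 differences of -1.32, -1.69 and -2.49, while Plce1, Synpo and Nes rose by 1.15, 0.74 and 0.27.

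Endothelial genes fell together. Every one of the 20 vessel markers was lower, by log2 differences whose median was -1.35 (camera adjusted p = 1.15e-12; adjusted p = 0.31 with an estimated correlation), and adjusted over the list alone the count was again 20. Plvap, the diaphragm protein of fenestrated endothelium, fell from 27542 ± 1257 to 6081 ± 626 (SD, n = 2), and Tek, the angiopoietin receptor, and Emcn fell 3.73-fold and 3.54-fold. Of 14 urothelial genes, markers of the lining of the renal pelvis, 11 fell and 1 rose (median -1.74, camera adjusted p = 0.000258; adjusted p = 0.479 with an estimated correlation), and adjusted over the list alone 12 fell and 1 rose. Between replicates 1 and 2 the median difference of the urothelial list was 0.73 in the KO-labelled and 0.40 in the WT-labelled libraries. Krt5 fell 9.87-fold and Psca 10.4-fold, whereas Krt20, also an injury-induced tubule keratin, rose 34.2-fold. Among 7 erythroid genes 5 fell and 1 rose (median -1.83, camera adjusted p = 0.00542; adjusted p = 0.479 with an estimated correlation), with 6 falls and 1 rise adjusted over the list alone; without KO replicate 2 the median was -1.19. Hba-a2 and Hbb-bs, which encode globin chains and have near-identical paralogs whose reads could be split, fell 3.56-fold and 4.09-fold, and Alas2, the erythroid heme synthesis enzyme, 5.14-fold. The others called were Slc4a1 and the transferrin receptor gene Tfrc, which fell, and Epb42, which rose by a log2 difference of 2.38. Slc4a1 is also a member of the intercalated cell list, so its fall need not come from red cells.

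Mitochondrial energy genes were lower. Of 30 nuclear-encoded respiratory chain subunits 29 fell and none rose, Ndufa2 having a log2 difference of -0.13 that did not pass the threshold, with a median log2 difference of -0.91 (camera adjusted p = 4.51e-12; adjusted p = 0.479 with an estimated correlation), and adjusted over the list alone 29 fell. Ndufs1 fell 2.55-fold and Sdha 2.02-fold. Thick ascending limb and proximal tubule markers fell in the same libraries (medians -1.53 and -1.35). These counts do not show in which cells the subunits fell. Ppargc1a, the coactivator of mitochondrial biogenesis, fell 4.07-fold. The sterol and fatty acid list that holds it went both ways, with 10 higher and 9 lower of 28, and the same counts adjusted over the list alone. Without WT replicate 1 the counts were 7 higher and 9 lower, and without KO replicate 2 they were 8 and 10. There the fatty acid oxidation genes Hadha and Acadm fell 2.13-fold and 2.17-fold and the cholesterol synthesis gene Cyp51 rose 1.93-fold. That list was not called (camera adjusted p = 0.955), and its median of 0.14 had the opposite sign to its mean of -0.09 and to the direction of the test.

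Genes of injured renal tubules rose almost without exception in the KO-labelled libraries. Of 32 such genes 31 rose and 1, Krt7, did not pass the threshold (log2 difference 0.34), with a median log2 difference of 1.82 (camera adjusted p = 7.35e-16; adjusted p = 0.31 with an estimated correlation), and adjusted over the list alone 32 rose. Lcn2, which encodes the urinary injury marker NGAL, rose from 540 ± 84.0 to 31070 ± 9649 (SD, n = 2), a 57.5-fold higher mean. Clu, clusterin, rose 19.6-fold to 83718 ± 14350, and Timp1, an inhibitor of metalloproteinases, 49.8-fold to 2168 ± 60.4. Spp1, osteopontin, stood at 427510 and 366760 in the KO-labelled libraries against 43049 and 46830. Havcr1, which encodes KIM-1, read 1343 in both KO-labelled libraries against 4.92 and 79.5, so its log2 difference of 5.94 carried an SE of 1.03. Sox9, a transcription factor of repairing tubules, rose 25.1-fold and Vcam1 7.58-fold.

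Interstitial matrix genes rose alongside. Of 30 extracellular matrix and fibrosis genes 27 rose and none fell (median 1.26, camera adjusted p = 7.72e-13; adjusted p = 0.31 with an estimated correlation), and adjusted over the list alone 28 rose. Col12a1, a fibril-associated collagen, rose 12.2-fold, Tgfbi 11.7-fold and Mmp14, a membrane-bound collagenase, 4.28-fold. Col1a1 rose from 13690 ± 2290 to 81690 ± 1818 (SD, n = 2). Among 20 markers of fibroblasts and pericytes 10 rose and 4 fell, with the same counts adjusted over the list alone. Mfap5 and Mfap4, microfibril components, rose 39.8-fold and 11.9-fold, while Ren1, renin, fell 15.5-fold, and Rgs5, Fbln5 and Tcf21 fell by log2 differences of -1.38, -0.88 and -0.48. That list was not called (median 0.36, camera adjusted p = 0.0715), but was without KO replicate 1 (adjusted p = 0.00887) and with no filter on low values (adjusted p = 0.0491; adjusted p = 0.72 with an estimated correlation in the main setting). Its falls numbered 2 without WT replicate 1 and with no variance trend, and its median was 0.22 without KO replicate 2.

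Most actin-responsive genes rose as well. Of 29 targets of SRF/MRTF and YAP/TEAD, transcription factors that respond to the actin cytoskeleton among other signals, 21 rose and 4 fell (median 0.76, camera adjusted p = 6.04e-06; adjusted p = 0.31 with an estimated correlation), with equal counts adjusted over the list alone. The falls numbered 1 without WT replicate 1, without KO replicate 1 and with no variance trend, and 2 without WT replicate 2. Ankrd1 rose 14.2-fold, Egr1 9.75-fold, Tagln2 3.49-fold and Tpm1 3.02-fold; Egr1 is also a member of the list of immediate early genes, which tissue handling can induce. Acta2, smooth muscle actin, rose 4.73-fold. Matrix and macrophage genes rose in the same libraries, and these counts do not show in which cells the targets rose. The members that fell were Fhl2, Amotl2, Lats2 and Crim1, by log2 differences of -0.77, -0.43, -0.33 and -0.26. Regulators of the Arp2/3 complex itself were mixed, with 15 of 32 higher and 4 lower (camera adjusted p = 0.0715), and adjusted over the list alone the counts were equal. Those that rose most were Nckap1l, Coro1a and Was, genes of blood-lineage cells, by 5.73-fold, 4.45-fold and 3.54-fold, and Cyfip2, a subunit of the WAVE complex, fell 3.95-fold. Wasf3, Pick1 and Abi2 also fell, by log2 differences of -0.89, -0.44 and -0.43. The rises numbered 8 without KO replicate 1 and 9 with no variance trend. This list was called higher after quantile normalization (adjusted p = 0.0362) and with no filter on low values (adjusted p = 0.0417; adjusted p = 0.479 with an estimated correlation in the main setting). Formins and other linear actin assembly factors split, with 5 higher and 6 lower of 20 (camera adjusted p = 0.724), and 5 and 7 adjusted over the list alone; with no variance trend 5 were higher and 4 lower. Fmnl1, Evl, Diaph3, Pfn1 and Fmn1 rose by log2 differences of 0.96, 0.79, 0.61, 0.57 and 0.45, while Daam2, Enah and Fhod1 fell 2.70-fold, 1.73-fold and 1.68-fold.

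Cell contact genes went both ways. Their counts are to be read beside the 4277 higher and 4051 lower of all 16253 genes tested. Of 32 tight junction, adherens junction and desmosome genes 11 rose and 9 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.945). The claudin genes parted: Cldn10 and Cldn19 fell 4.89-fold and 2.45-fold, and Cldn4, Cldn3 and Cldn7 rose 6.09-fold, 3.01-fold and 2.49-fold. Cgnl1, paracingulin, fell 3.37-fold. Among 31 integrin, laminin and focal adhesion genes 11 rose and 7 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.18). Itga2, Lama3 and Itgav rose 7.71-fold, 2.82-fold and 2.26-fold.

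Many immune cell markers rose, those of mononuclear phagocytes among them. Of 22 macrophage and dendritic cell genes 21 rose and none fell (median 2.64, camera adjusted p = 7.72e-13; adjusted p = 0.31 with an estimated correlation), and adjusted over the list alone 21 rose. H2-Aa, a class II antigen presentation gene, had a log2 difference of 0.78 that passed the threshold without WT replicate 1 (1.38, adjusted p = 0.0132) or without KO replicate 2 (1.12, adjusted p = 0.0214). C1qa and C1qc, which encode complement C1q chains, rose 6.37-fold and 5.52-fold, Lyz2, lysozyme, 7.63-fold, and Mrc1, the mannose receptor, 4.39-fold. Of 13 lymphocyte genes 7 rose and none fell (median 0.69, camera adjusted p = 0.0101; adjusted p = 0.479 with an estimated correlation), again equal adjusted over the list alone; without WT replicate 1 the median was 1.12. Thy1, which fibroblasts and neurons also express, rose 13.0-fold and Cd4, which mouse macrophages can also carry, 4.92-fold. Klrb1c had 3 reads in the WT-labelled and 48 in the KO-labelled libraries, a ratio of 16.2 (95% interval 5.23 to 81.4). The lymphocyte call was lost without WT replicate 2 (adjusted p = 0.0818) and without KO replicate 2 (0.116); 4 members rose in the first case, 3 rose and 1 fell in the second, and 4 rose without KO replicate 1. Of 6 neutrophil genes 4 rose and none fell (median 2.61, camera adjusted p = 0.0113; adjusted p = 0.365 with an estimated correlation), with 5 adjusted over the list alone. Another 8 members did not pass the filter; with no filter 5 of 14 rose and the median was 1.30, and with a pseudocount of 5 it was 1.83. Mmp9 rose 11.6-fold and Il1r2 14.4-fold, both also made by macrophages, and Csf3r rose by a log2 difference of 0.62. Mmp8 had 3 reads in the WT-labelled and 58 in the KO-labelled libraries, a ratio of 19.6 (95% interval 6.38 to 97.8).

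Inflammatory signalling genes rose in 25 of 28 cases and fell in 1 (median 2.10, camera adjusted p = 3.02e-09; adjusted p = 0.31 with an estimated correlation), with equal counts adjusted over the list alone. C3, the central complement component, rose from 229 ± 65.8 to 7605 ± 682 (SD, n = 2), and Icam1, Cxcl16 and Csf1 rose 4.86-fold, 4.35-fold and 3.48-fold. The member that fell was Cxcl12, by 2.53-fold. Interferon-stimulated genes split, with 12 higher and 4 lower of 28 and the same counts adjusted over the list alone (camera adjusted p = 0.55). Rsad2, Ifi44, Ifit2 and Ifit3 fell by log2 differences of -2.22, -1.28, -0.87 and -0.63, while Isg20 and Oas2 rose 2.51-fold and 2.32-fold. Part of this list stood apart in a WT-labelled library: its median lay 0.52 higher in WT replicate 1 than in WT replicate 2, and Gbp2, a guanylate-binding protein gene, read 2353 and 397 there. Without WT replicate 1 the list was called higher (median 0.58, adjusted p = 0.0106; adjusted p = 0.977 with an estimated correlation and all libraries), and without WT replicate 2 its median was -0.24 (adjusted p = 0.48), with 5 members higher and 7 lower. The counts were 6 higher and 5 lower without KO replicate 1, 7 and 4 with no filter on low values, 2 and 3 with no variance trend and 6 and 4 with a robust one. Gbp2 itself was called higher without WT replicate 1 (log2 difference 1.89, limma adjusted p = 0.000831) and lower without WT replicate 2 (-0.67, adjusted p = 0.0121).

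Among 24 p53 targets and apoptosis genes 12 rose and 2 fell (median 0.35, camera adjusted p = 0.0113; adjusted p = 0.365 with an estimated correlation), and adjusted over the list alone 15 rose and 2 fell. With no variance trend 9 rose and 1 fell. Pmaip1, which encodes NOXA, rose 9.32-fold and Gdf15, a stress-induced cytokine gene, 4.51-fold, whereas Sesn1 fell by a log2 difference of -0.58. Immediate early genes, which tissue handling can also induce, were higher for 15 and lower for 4 of 24 (median 1.19, camera adjusted p = 0.000581; adjusted p = 0.31 with an estimated correlation), with equal counts adjusted over the list alone. Egr2 rose 57.4-fold, Junb 5.17-fold and Jun 3.32-fold. The flow-responsive factor Klf2 and the heat shock genes Hspa1b, Hsph1 and Hspa1a fell by log2 differences of -0.97, -0.64, -0.56 and -0.27; Hspa1a and Hspa1b are near-identical copies between which reads can be split. Most proliferation genes did not pass the threshold: 7 of 30 were higher and 2 lower (camera adjusted p = 0.113), and 6 and 1 adjusted over the list alone. The replication licensing genes Mcm2, Mcm3 and Mcm5 rose 1.44-fold, 1.49-fold and 1.45-fold, and Kif23 and Rrm2 fell by log2 differences of -0.50 and -0.44. The cell cycle list was called higher only without KO replicate 1 (adjusted p = 0.00415; adjusted p = 0.72 with an estimated correlation and all libraries), while without KO replicate 2 its median was 0.0519, with 4 members higher and 4 lower. Of 16 nephron progenitor and developing nephron genes 8 fell and 4 rose (camera adjusted p = 0.306), and 8 and 5 adjusted over the list alone. The falls numbered 5 without WT replicate 1, with DESeq2 and with a minimum mean of 50. Wnt4 rose 5.12-fold and Lhx1, Ret and Crym by log2 differences of 1.10, 0.84 and 0.71, while Wnt11, Ccnd1 and Pax2 fell by log2 differences of -1.25, -1.12 and -1.14. Cilium and cystic kidney genes were 8 lower and 4 higher of 30, and 8 and 3 adjusted over the list alone (camera adjusted p = 0.979); the rises numbered 2 without WT replicate 2, without KO replicate 1 and with no variance trend. Their median of 0.11 had the opposite sign to the mean of -0.02 and to the direction of the test. Nek8, Ift80, Pkd1 and Pkd2 had log2 differences of -0.84, -0.71, -0.48 and -0.41, and Arl13b, Bicc1, Ift57 and Pkhd1 of 0.64, 0.43, 0.37 and 0.29.

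Several calls depended on single libraries or settings. Without WT replicate 1 those of Kap, Csf3r, Amotl2, Lats2, Crim1, Tmem45b, Cldn16, Tspan8, Tcf21, Fbln5, Crym, Nes, Kif23, Rrm2 and Hspa1a were lost (limma adjusted p from 0.052 to 0.184). Leaving out WT replicate 2 ended the calls of Actr2, Csf3r, Diaph3, Lats2, Crim1, Cldn16, Tspan8, Crym, Ret, Nes, Rrm2, Slc38a2, Pkhd1, Ift57 and Hspa1a (adjusted p from 0.0508 to 0.213). Leaving out KO replicate 1 ended those of Actr2, Amotl2, Lats2, Crim1, Tmem45b, Cldn16, Tspan8, Tcf21, Ret, Nes, Kif23, Rrm2, Pkhd1, Ift57 and Hspa1a (adjusted p from 0.0548 to 0.231). Without KO replicate 2 Csf3r, Diaph3, Crim1, Cldn16, Crym, Slc38a2, Pkhd1 and Hspa1a were no longer called (adjusted p from 0.0643 to 0.23), while Krt7 was (adjusted p = 0.00968). With no filter on low values Cldn16, Crym, Hspa1a, Ift57, Lats2 and Rrm2 were not called (adjusted p from 0.0521 to 0.0799), and after quantile normalization Cldn16, Crym, Csf3r, Ift57 and Lats2 were not (adjusted p from 0.0536 to 0.0621). Cldn16 also missed the threshold with TMM scaling, edgeR and DESeq2 (adjusted p = 0.0542, 0.0566 and 0.0755), Rrm2 with upper-quartile scaling (0.0536) and Hspa1a with DESeq2 (0.0531), which called Krt7 (0.0457). With a robust variance trend Nccrp1, Slc12a3, Havcr1, Slc34a1 and Kap were not called (adjusted p from 0.0542 to 0.144). With no variance trend Actr2, Slc34a1, Kap, Amotl2, Lats2, Crim1, Tmem45b, Cldn16, Tspan8, Tcf21, Fbln5, Crym, Nes, Ifit3, Rrm2, Slc38a2, Pkhd1, Ift57 and Hspa1a were not (adjusted p from 0.051 to 0.129).

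**Figure D3:**
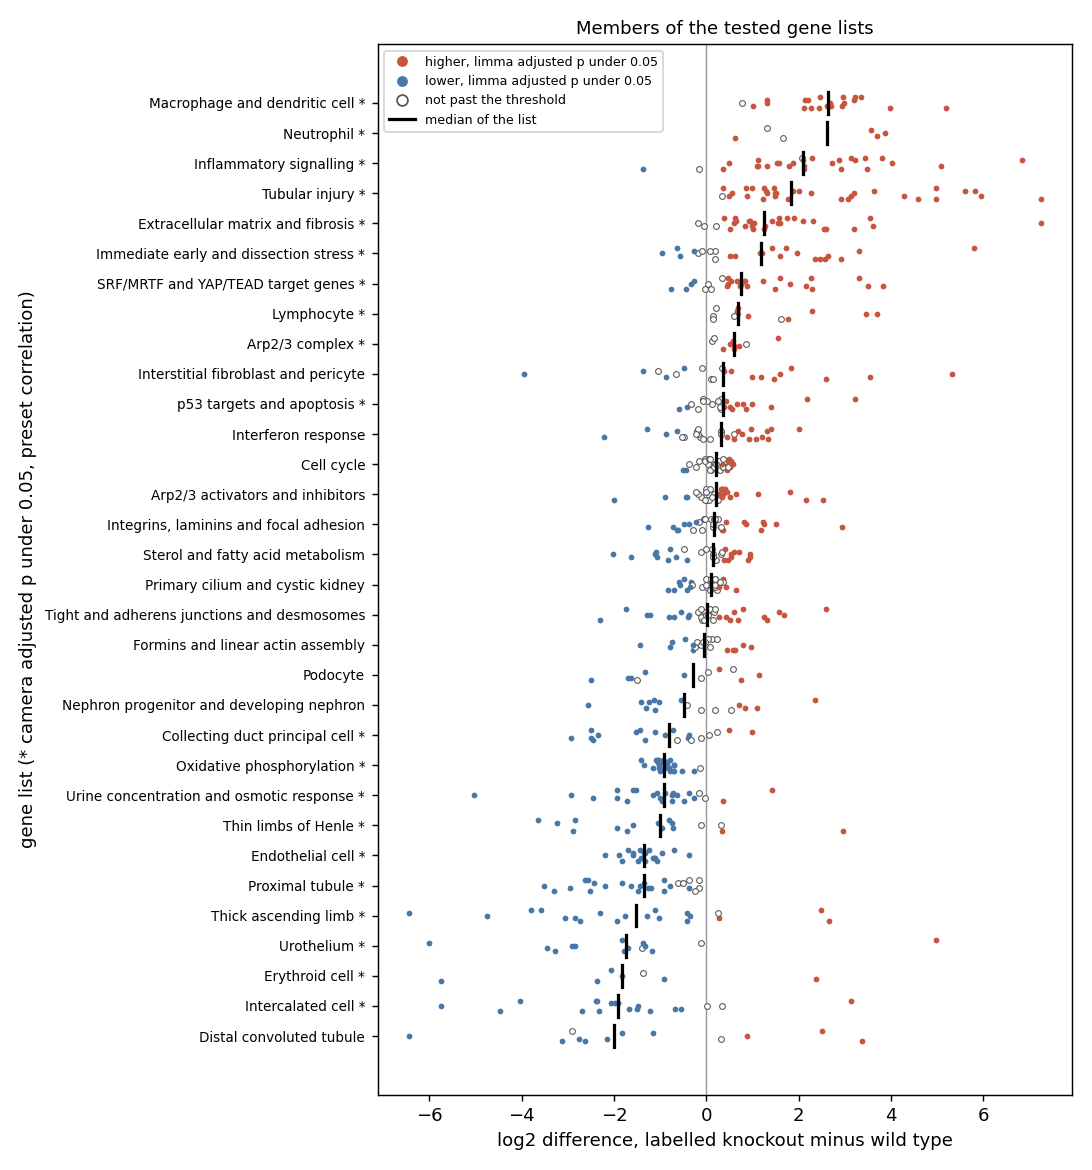
Log2 difference (KO-labelled minus WT-labelled) of each tested member of the 32 gene lists, filled where limma's adjusted p was under 0.05, with a black line at the median of each list. Lists are ordered by median, from distal convoluted tubule at -1.99 to macrophage and dendritic cell at 2.64, and an asterisk marks the 20 lists called by camera at its preset correlation.

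In all, 10 lists were called higher, 10 lower and 12 not called. With the estimated correlation 0 lists were called, the smallest adjusted p being 0.31. The female transcript Xist was abundant in all 4 libraries, at 36930 and 27873 in the WT-labelled and 34400 and 37573 in the KO-labelled, and Ddx3y, a Y-linked gene, read at most 15.9 normalized counts. With 2 libraries a group, the smallest p of a two-sided exact permutation test is 0.333, so the calls rest on limma's model, which pools the spread across genes.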

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

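The alternatives were fixed before the data were examined, but counts of called list members without 1 library were added after the data were seen. Across other pseudocounts, filters, scalings, variance models and count tools, 3424 to 4315 genes were higher and 3306 to 4230 lower, and leaving out 1 library gave 3175 to 3646 and 3084 to 3490. Between 6201 and 8316 of the 8328 calls were shared with each alternative in the same direction, and 0 turned sign. A log2 difference of at least 1 left 1745 higher and 1536 lower, by construction. Actr3 stayed higher in the KO-labelled libraries, with log2 differences from 0.64 to 0.78 when 1 library was left out, and adjusted p from 5.37e-12 with DESeq2 to 0.0116 with no variance trend. The lists called higher numbered 9 to 12 and those called lower 10 to 11 without 1 library, 12 and 10 with fry, and 0 and 0 with an estimated correlation, where the smallest adjusted p was 0.31; a raised list in simulated data was missed in that setting as well. That simulation drew genes without correlation, whereas the correlations estimated here ranged from -0.0418 to 0.892 across the lists. It cannot show whether the calls here were lost through correlated members or through few residual degrees of freedom. The replicate numbers did not pair the libraries (r = -0.0564 across genes between the replicate differences of the groups), and a replicate block gave 3810 higher and 3619 lower genes, 11 and 11 lists, and an adjusted p of 0.000742 for Actr3. With the block the distal convoluted tubule (adjusted p = 0.0362) and fibroblast lists (0.0428) were called, against 0.72 for both with an estimated correlation and no block. Of genes named in the text the block added the call of H2-Aa (0.00224) and left out those of Lats2 (0.0524), Crim1 (0.0646), Cldn16 (0.102), Nes (0.0636), Pkhd1 (0.0524) and Hspa1a (0.0994), with unchanged log2 differences, and 2 targets of SRF/MRTF and YAP/TEAD fell with it. The fry test called the lists of Arp2/3 regulators (adjusted p = 0.00986), integrins (0.0148) and sterol metabolism (0.0346) as well, against 0.479, 0.479 and 0.979 with an estimated correlation. Some values near 0 changed sign without 1 library: Xist ranged from -0.0388 to 0.37, Umod from -0.0227 to 0.54, Scnn1b from -0.30 to 0.0899, Gata3 from -0.16 to 0.26, Atp6v0d2 from -0.15 to 0.17 and Ndufa2 from -0.28 to 0.0118. Gbp2, at 0.61 with all libraries, ranged from -0.67 to 1.89 and passed the threshold in opposite directions, lower without WT replicate 2 (adjusted p = 0.0121) and higher without WT replicate 1 (0.000831). List medians without 1 library ranged from -0.0726 to 0.11 for junctions, -0.24 to 0.58 for interferon and 0.0630 to 0.23 for sterol metabolism. The direction of the list test also turned for junctions with fry (median 0.0135), for cilium genes with no filter (0.11), upper-quartile scaling (0.11) and quantile normalization (0.12), and for sterol metabolism with no filter (0.14) and quantile normalization (0.15); the cause was not tested. Of single genes, leaving out a library kept the direction and side of the threshold in 839 cases, ended a call in 56 and added one in 6, and the other settings in 2670, 51 and 8. Read depth lay between 36482238 and 40784436 in each library and sets a limit for genes with few reads, such as those near 0 in the WT-labelled libraries.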

Other observations

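The test of sex, the sign of the cortical medians and the odds ratio of calls near Actr3 were fixed before the results were seen; all other tests below, among them those of the medullary medians and of the share of genes called outside the segment, and the gene families were chosen after.

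Gene families that were not fixed as lists were looked at as well. Of 79 cytosolic ribosomal protein genes 72 were higher and 0 lower (limma, median log2 difference 0.62), and 71 were higher with quantile normalization or DESeq2. Rps6 rose from 4893 and 4882 to 7777 and 6991. Of 77 mitochondrial ribosomal protein genes 3 were higher and 22 lower (median -0.209). Of 32 Hox genes 2 were higher and 14 lower (median -0.287). Of 16 histone genes, most of them replication-dependent, 15 were lower and 0 higher (median -2.95). H1f2, a linker histone gene, fell from 9378 and 10220 to 1122 and 945, and H2ac6 by a log2 difference of -3.54, while H1f10, whose transcript is polyadenylated, had 0.34 (adjusted p = 0.0917). The medians of these families kept their sign under all 5 other scalings and count tools. How polyadenylated the counted RNA was in each group was not tested, and histone transcripts without a tail depend on it.

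Mononuclear phagocyte genes outside the rule rose strongly too. Itgax, an integrin of dendritic cells and macrophages, rose 39.0-fold and Trem2, a lipid receptor of macrophages, 16.2-fold. Among matrix genes Col3a1 and Fn1 rose 3.06-fold and 3.35-fold. Il6 had 2 reads in the WT-labelled and 48 in the KO-labelled libraries, a ratio of 24.3 (exact binomial 95% interval 6.38 to 207), and Tnf rose 12.8-fold.

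Actr3 was higher in both KO-labelled libraries. An exchange of 1 library between the groups, or 1 wrong label, is argued against by the correlations: the highest between the groups was 0.916, below both values within a group. An exchange of both labels would turn the log2 difference of 0.71 into a fall of the same size. It would also make the wild-type animals those with 31 of 32 injury genes higher. No value here shows directly which animals carried Cre, so an exchange of both labels cannot be told apart from labels that are right. Reads from exons that Cre leaves in place, or from cells without Cre, may hide a deletion: Actr3 lay 0.12 above the median of the 9 other subunits, within their range of 0.13 to 1.55, and counts per exon would be needed to decide. The rise as a response of the tissue to the loss of Arp3 also stays open as a hypothesis.

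The large number of genes called, with tubule markers lower and injury genes higher, was weighed against sex, dissection and strain. Sex is argued against, since Xist (log2 difference 0.16) and Ddx3y overlapped between the groups. The medians of the 3 cortical lists all lay below 0 beyond the replicate difference. The test fixed in advance asked this of a smaller share of cortex. Podocytes did not meet it without WT replicate 2, at -0.18, or without KO replicate 1, at -0.19. A smaller share of cortex alone would raise markers made only in the medulla. The highest median of the principal cell, thick ascending limb and thin limb lists was -0.80, which argues against it as the whole cause. That holds only for markers that the cortex does not share, and a smaller share of cortex beside another change stays open. For the cortical markers alone, the podocyte median was -0.30 and podocyte genes were called both ways. There a share of cortex cannot be told apart from the genotype. Strain differences within a segment around the floxed gene are argued against as the whole cause, since 51.2% of the tested genes outside 20 Mb of Actr3 were called, but for the 93 of 159 genes called within it they cannot be told apart from the genotype: the odds ratio of 1.34 lay under the bound of 1.5 fixed in advance, and its 95% interval of 0.969 to 1.88 holds both 1 and that bound (Fisher's exact test, two-sided, p = 0.0672). Effects of such a segment on distant genes, and other differences between mixed-background litters, stay open.

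The lower tubule markers may come from fewer tubule cells, from RNA of other cells or from lower expression per cell. Cell loss or dilution alone would make markers fall alike, provided that each is made by its segment alone. Of 76 members of the 4 medullary lists, 60 (78.9%) had a 95% interval that left out the median of their own list. Umod and Slc12a1 of the same segment lay far apart. The members thus did not fall alike, but members that other cells also make would part under cell loss too. Endothelial markers, which are not of tubule cells, fell as well (20 of 20). The spread therefore cannot decide between cell loss, dilution and lower expression per cell. The authors' size factors move all genes of a library alike. They therefore cannot change the difference of the 4 medians from that of all tested genes, -0.81 at the highest, and this difference is no test of them. With TMM, upper-quartile and quantile scaling the principal cell median, the highest of the 4, was -0.813, -0.8 and -0.786. A change of the total RNA per cell was not measured. A change of expression within tubule cells labelled knockout is a hypothesis that these bulk values leave open.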
